A study of Homo sapiens with 34 samples.

How the data were processed

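RNA was sequenced from 6 human blood cancer cell lines, each left untreated or treated with 10 µM etoposide for 4 hours, per the labels. Etoposide is a drug that traps DNA topoisomerase II on cut DNA and so leaves double-strand breaks. NALM6 and 697 are pre-B cell lines, RAMOS is a mature B cell line, JURKAT is a T cell line, and THP1 and U937 are myeloid lines, per the series description. Total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit, per the labels' protocols.

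The deposited count files hold whole-number read counts per gene symbol, 1 file per library, and per the file names they come from htseq-count. HISAT, HTSeq, DESeq2 and the genome build hg19 are named, per the submitters' processing notes, and their versions are not given in the sources used here. Each of the 34 deposited files lists 23368 gene symbols and no line for unassigned reads, so the share of unassigned reads is unknown. The authors also deposited 1 comparison table per line, which holds a log2 fold change and its standard error in log2 units, per the file headers. The same deposited tables hold a Wald score and an adjusted p-value, per the file headers. Those tables were read only to compare their calls and signs with the counts, and no other value comes from them.

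The labels put 17 libraries in control groups and 17 in etoposide groups. Every group had 3 libraries except 697 etoposide and U937 control, which had 2 each. The origin of the replicates is not stated, so every p-value measures only the spread between these samples, which may be technical. The file names carry 4 library pools. The NALM6 and 697 controls lay in 1 pool and their etoposide libraries in another, together with all JURKAT libraries, so pool and treatment cannot be separated in the pre-B lines. RAMOS, JURKAT, THP1 and U937 each lay within 1 pool.

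Counts were read in R 4.3.3. Within each line, genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10, scaled by TMM and tested with the robust quasi-likelihood F test of edgeR. All gene tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Log2 fold changes are printed with their standard error, and CPM values (counts scaled to 1 M per library) are group means with the standard deviation between libraries. Differences of the etoposide effect between lines were tested as contrasts in 1 edgeR fit of all 34 libraries with a coefficient for each line and treatment. The CPM of that fit share 1 scaling over all lines and so differ a little from the CPM of the separate fits. The contrasts were the pre-B lines minus the 4 other lines, the myeloid lines minus RAMOS and JURKAT, NALM6 minus 697, and THP1 minus U937.

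A fold change against a group without any read was given as a lower bound against a floor of 3 counts over the group's libraries. With 1 to 3 reads in the lower group, the ratio of counts was given with a 95% counting interval. Intervals and floors cover counting error only, since these are PCR reads without molecular identifiers.

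The genes named were chosen by rule. Within a line these were the 6 highest and 6 lowest log2 fold changes among called genes with an average log2 CPM of at least 1 and with every etoposide library beyond every control. For each contrast the 10 largest differences per direction were taken, and for genes called the same way in all 6 lines up to 10 per direction. Up to 4 members of each gene list with the smallest adjusted p were added, and CDKN1A, MDM2, MYC, TOP2A and TOP2B were always reported. Some named genes and 1 gene list that the rules covered are not reported here. Antisense, readthrough and unnamed loci were passed over.

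The test of 18 gene lists used camera of limma 3.58.1 on voom-weighted log2 CPM with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. A second camera run estimated the correlation from the data, and its adjusted p is given wherever it ended a call. Calls were lost in that run also where the estimate lay below 0.01, so a loss is not by itself a sign of correlated members. The lists were p53 targets, G2/M genes, G1/S genes under E2F control, histone genes, NF-κB targets, interferon-stimulated genes, immediate-early genes, integrated stress response genes, unfolded protein response genes, heat shock genes, the BCL2 family, double-strand break repair genes, topoisomerases with the enzymes TDP1 and TDP2, ribosome biogenesis genes, pre-B and V(D)J genes, genes of the pre-B response to RAG breaks, myeloid differentiation genes and T cell signalling genes. Another 6 lists were described only as summed CPM, namely markers of pre-B, B, T, NK, myeloid and erythroid cells. The lists, contrasts, naming rules and tests of the comparisons were fixed before the data were examined, but some tests of explanations were not.

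Gene spans came from the GENCODE v29 annotation on GRCh38 and were matched by name. A span was found for 21601 of the 23368 symbols, 20151 by the current symbol and 1450 by an older symbol. In each library the median log2 CPM of genes spanning under 20 kb was subtracted from that of genes spanning over 100 kb, with a pseudocount of 0.5 CPM and a mean CPM of at least 1 in the line. The treatment effect on that score was tested within each line by an exact permutation test. Over all lines, treatment was permuted within lines with 100000 resamples. Both tests were two-sided.

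Total counts per library ran from 8.18 to 37.1 M. At the depth of NALM6, the floor of 3 counts over the control libraries corresponded to 0.0497 CPM. The edgeR tests of the 6 lines and of the pre-B contrast were tried on simulated counts with 200 changed genes. Of genes changed 1.5-fold, the edgeR test recovered 85.1% in NALM6, 83.6% in 697, 95.5% in RAMOS, 77.6% in JURKAT, 86.6% in THP1 and 92.5% in U937. Of genes changed 2-fold, it recovered 98.5% in NALM6, 95.5% in 697, 98.5% in RAMOS, 86.6% in JURKAT, 95.5% in THP1 and 98.5% in U937. False calls made up 4.55% of calls in NALM6, 4.12% in 697, 4.85% in RAMOS, 2.78% in JURKAT, 3.59% in THP1 and 6.76% in U937. The pre-B contrast recovered 98.5% of genes simulated 1.5-fold apart, with 5.24% false calls. In simulated NALM6 libraries, the list test found the raised list and called 0 others. The simulated genes varied independently, so false list calls from correlated members were not tried. In the data the estimated correlation was as high as 0.416, for immediate-early genes in JURKAT. A simulated lowering of long genes in RAMOS by 0.585 on the log2 scale was recovered as −0.559.

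Alternatives to the main choices were the RLE scaling of DESeq2, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, all libraries in 1 fit, a 2-fold threshold, and leaving out each library in turn. For long genes they were a limit of 200 kb, a mean CPM of at least 5, and long and short genes matched on mean CPM. Levels of sex-linked genes were left out.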

Results

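The series asked how 6 immune cell lines change their gene expression when etoposide breaks their DNA, per the series description. It held 34 libraries, 17 untreated and 17 treated. Total counts, in units of M (mega), ran from 11.1 to 34.2 M per library in NALM6, from 14.03 to 23.3 M in 697, from 8.18 to 22.8 M in RAMOS, from 9.58 to 20.4 M in JURKAT, from 18.7 to 24.8 M in THP1 and from 22.2 to 37.1 M in U937. Between 13917 and 17507 genes had a count in a library. In NALM6 these were 13917 to 14978 in controls and 15908 to 16132 in etoposide libraries. In 697 they were 14355 to 14738 and 16408 to 17097. The treated libraries of NALM6 and 697 were no deeper than the deepest controls. Treatment coincided with library pool there, so the cause of these rises cannot be told. In U937, within 1 pool, the ranges were 15558 to 15857 and 15926 to 16301. Both ranges overlapped in RAMOS, JURKAT and THP1. Marker genes were in place for each lineage before treatment. Pre-B markers such as the surrogate light chain gene IGLL1 summed to 3201 ± 10.1 CPM (SD, n = 3) in NALM6 controls and to 3299 ± 15.6 CPM (n = 3) in 697 controls. B cell markers summed to 3215 ± 24.8 CPM (n = 3) in RAMOS controls, T cell markers to 2572 ± 78.7 CPM (n = 3) in JURKAT controls, and myeloid markers to 4845 ± 152 CPM (n = 3) in THP1 controls and 3375 ± 28.6 CPM (n = 2) in U937 controls. NK markers were highest in U937 controls, at 259.7 ± 2.32 CPM (n = 2). Erythroid markers summed to at most 0.577 CPM in every group. In the text below, means and SD cover 3 libraries per group, except 2 for 697 etoposide and U937 control.

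The first comparison asked what etoposide changed in NALM6. CDKN1A, which encodes the cell cycle inhibitor p21, rose 40.4-fold, from 166 ± 2.91 to 6693 ± 206 CPM (edgeR adjusted p = 5.67e-54). EPHA2, a receptor kinase gene, rose from no reads to 14.4 ± 0.463 CPM, at least 276-fold. GDF15, a stress cytokine gene, rose from no reads to 9.77 ± 0.836 CPM, at least 186-fold. EGR3, an immediate-early transcription factor gene, went from 1 read to 1909, a ratio of 2338 (95% counting interval 419 to 92370). RAG1, which cuts antigen receptor genes, fell from 652 ± 22.8 to 44.0 ± 6.18 CPM, a log2 change of −3.89 ± 0.0657 (SE). EBF1, a transcription factor of the B lineage, fell from 309 ± 11.2 to 26.2 ± 0.545 CPM, and the pattern recognition gene TLR10 fell by 4.10 on the log2 scale. The chemokine gene CCL4 went from no reads to 41.5 ± 1.77 CPM, at least 794-fold, and the pseudogene RNF5P1 fell by 4.05 on the log2 scale, but both have near-identical copies, so their reads are uncertain.

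In NALM6 the gene lists moved as follows, with the same member counts when p was adjusted over the list alone. Of 38 measured p53 targets, 37 rose, 0 fell and 1 did not pass (camera adjusted p = 2.07e-21, median log2 change 2.84). Among them BBC3, which promotes apoptosis, rose 40.1-fold and PHLDA3, an AKT inhibitor gene, rose 48.9-fold. Of 31 G2/M genes, 30 fell and 1 rose (camera adjusted p = 3.16e-12), with the mitotic kinase gene PLK1 at −3.79 ± 0.0691 and CCNB1, which encodes cyclin B1, at −3.08 ± 0.0656 on the log2 scale. NF-κB targets rose in 18 of 19 members and fell in 1 (camera adjusted p = 1.44e-10), with TNFAIP3, a feedback inhibitor, up 17.4-fold and the adhesion gene ICAM1 up 22.9-fold. Immediate-early genes rose in 23 of 24 members and fell in 1 (camera adjusted p = 3.53e-11), with ATF3 up 272-fold and JUN up 147-fold. Of 25 pre-B and V(D)J genes, 20 fell, 4 rose and 1 did not pass (camera adjusted p = 5.54e-07, but adjusted p = 0.117 with an estimated correlation). Summed pre-B markers fell to 1162 ± 33.1 CPM and B cell markers to 755 ± 33.2 CPM, from 1532 ± 54.6 CPM, given as values without a test of the sum. Genes of the response to RAG breaks rose in 6 of 7 members and fell in 1 (camera adjusted p = 0.000511, but adjusted p = 0.0558 with an estimated correlation), among them CD69, an activation marker gene, by 8.36 on the log2 scale. The G1/S list was lower, with 17 members down, 7 up and 4 not past (camera adjusted p = 0.0223, but adjusted p = 0.118 with an estimated correlation).

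Of 12589 genes tested in NALM6, 10263 were called, 5195 up and 5068 down. A change of at least 2-fold was called for 3826 of them. Every etoposide library lay beyond every control for 81.6% of the tested genes, against 10% by chance. Library pool and treatment coincided in this line, so none of these values separates the pair.

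In 697, the second pre-B line, EBI3, which encodes a cytokine subunit, rose from no reads to 57.7 ± 7.12 CPM, at least 1125-fold. CD80, a T cell co-stimulator gene, rose from no reads to 24.7 ± 0.957 CPM, at least 494-fold. CDKN1A rose 28.9-fold, from 152 ± 4.05 to 4396 ± 86.4 CPM (edgeR adjusted p = 1.08e-19). MYC, a growth-promoting transcription factor gene, fell from 776 ± 28.9 to 64.5 ± 8.98 CPM, a log2 change of −3.60 ± 0.0820. RAG1 fell from 219 ± 2.29 to 7.41 ± 1.38 CPM, FAM65B by 4.65 on the log2 scale, and PSRC1, a spindle gene, by 3.89. TOP2B, a topoisomerase II gene, fell from 2588 ± 82.8 to 508 ± 6.12 CPM.

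All 39 measured p53 targets rose in 697 (camera adjusted p = 2.22e-18, but adjusted p = 0.0565 with an estimated correlation), among them GADD45A at 24.1-fold and FDXR at 18.04-fold. G2/M genes fell in 30 of 31 members (camera adjusted p = 1.22e-12, but adjusted p = 0.0565 with an estimated correlation). G1/S genes fell in 26 of 28 members and rose in 1 (camera adjusted p = 1.19e-08, but adjusted p = 0.0565 with an estimated correlation), with MCM6, a replication helicase gene, at −1.55 ± 0.0525. NF-κB targets rose in 20 of 21 members (camera adjusted p = 2.49e-10, but adjusted p = 0.0565 with an estimated correlation), with ICAM1 up 139-fold. Immediate-early genes rose in 22 of 24 members and fell in 2 (camera adjusted p = 5.98e-08, but adjusted p = 0.0565 with an estimated correlation). All 22 measured histone genes rose (camera adjusted p = 1.48e-05, but adjusted p = 0.0726 with an estimated correlation), such as HIST2H2BE at 7.65-fold, though histone genes have near-identical copies and their reads are uncertain. The 6 topoisomerase and TDP genes all fell (camera adjusted p = 0.000942, but adjusted p = 0.0726 with an estimated correlation). Repair genes fell in 22 of 31 members and rose in 5 (camera adjusted p = 0.00293, but adjusted p = 0.0726 with an estimated correlation). Pre-B and V(D)J genes fell in 18 of 25 members and rose in 5, or 6 when adjusted over the list alone (camera adjusted p = 2.95e-05, but adjusted p = 0.0565 with an estimated correlation). Summed pre-B markers stood at 1035 ± 19.1 CPM after etoposide. The other counts were the same when adjusted over the list alone. Genes of the response to RAG breaks rose in 6 of 7 members and fell in 1 (camera adjusted p = 0.00779, but adjusted p = 0.102 with an estimated correlation), with CD40, a B cell co-stimulation receptor gene, at 366-fold. Myeloid differentiation genes rose in 7 of 8 measured members and fell in 1 (camera adjusted p = 0.0263, but adjusted p = 0.137 with an estimated correlation), with the integrin gene ITGAM going from 2 reads to 2673. Summed myeloid markers went from 29.7 ± 1.84 to 47.7 ± 2.79 CPM.

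Of 13439 genes tested in 697, 10257 were called, 5295 up and 4962 down, and 4485 of them changed at least 2-fold. For 83.5% of the tested genes both etoposide libraries lay beyond every control, against 20% by chance. As in NALM6, pool and treatment coincided, and the etoposide group held only 2 libraries.

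In RAMOS, the mature B cell line, EBI3 rose 285-fold, from 0.0754 ± 0.0698 to 29.2 ± 1.83 CPM (edgeR adjusted p = 1.02e-34). This fold is the edgeR estimate, which lies below the ratio of the means, and the control level lay near the floor of 0.0565 CPM. TNFAIP2, an inflammation gene, rose 61.3-fold to 127 ± 1.71 CPM, and BCL2A1, an apoptosis inhibitor gene, rose 40.5-fold to 7.23 ± 0.0359 CPM. BACH2, a repressor that keeps B cells undifferentiated, fell from 742 ± 6.24 to 43.2 ± 1.54 CPM, a log2 change of −4.10 ± 0.0462. PLK1 fell from 243 ± 6.14 to 8.35 ± 0.495 CPM. MDM2, a ubiquitin ligase gene, fell by 1.58 on the log2 scale (SE 0.0409), while CDKN1A rose 4.59-fold to only 6.996 ± 0.635 CPM.

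Of 33 measured p53 targets in RAMOS, 13 rose, 9 fell and 11 did not pass, and the list was not called (camera adjusted p = 0.616, median log2 change 0.12). Its member FAS, a death receptor gene, rose 29.9-fold. All 28 G1/S genes rose (camera adjusted p = 2.52e-18, but adjusted p = 0.0652 with an estimated correlation), with the cyclin genes CCNE2 at 4.69-fold and CCNE1 at 4.48-fold. G2/M genes fell in 29 of 30 members and rose in 1 (camera adjusted p = 1.83e-16, but adjusted p = 0.0652 with an estimated correlation). NF-κB targets rose in 17 of 19 members and 2 did not pass (camera adjusted p = 3.10e-14), with CD83, an activation marker gene, at 15.5-fold and NFKB2 at 9.11-fold. Integrated stress genes rose in 17 of 19 members and fell in 1 (camera adjusted p = 1.48e-09, but adjusted p = 0.0918 with an estimated correlation), with the asparagine synthetase gene ASNS at 2.66-fold. The pre-B and V(D)J list fell in 18 of 23 members and rose in 2 (camera adjusted p = 2.01e-08, but adjusted p = 0.0652 with an estimated correlation), with POU2AF1, a B cell coactivator gene, at −2.42 ± 0.0404. Immediate-early genes rose in 13 of 18 members and fell in 5 (camera adjusted p = 0.00260, but adjusted p = 0.273 with an estimated correlation). The list of the response to RAG breaks rose in 5 of 7 members and fell in 1 (camera adjusted p = 0.000318, but adjusted p = 0.0652 with an estimated correlation). Each of these counts was the same when adjusted over the list alone. Summed B cell markers stood at 2182 ± 21.5 CPM after etoposide.

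Of 12240 genes tested in RAMOS, 8535 were called, 4191 up and 4344 down, and 1895 changed at least 2-fold. Every etoposide library lay beyond every control for 71.1% of the tested genes, against 10% by chance.

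In JURKAT, the T cell line, EGR1 rose 6.39-fold, from 46.2 ± 3.33 to 296 ± 68.1 CPM (edgeR adjusted p = 0.00214), FOS 4.73-fold and JUN 4.41-fold, all 3 encoding rapidly induced transcription factors. PIF1, a helicase gene, fell from 41.9 ± 5.50 to 3.68 ± 0.779 CPM, a log2 change of −3.50 ± 0.143. PLK1 fell by 2.86 and KIF20A, a mitotic motor gene, by 2.29 on the log2 scale. FAM72B fell by 2.29 and FAM72D by 2.10, which are near-identical copies, so their reads are uncertain. CDKN1A rose 1.91-fold to 27.2 ± 1.25 CPM, whereas MDM2 did not pass (log2 change 0.07 ± 0.0574, adjusted p = 0.472).

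All 31 G2/M genes fell in JURKAT (camera adjusted p = 8.62e-65), and 27 of 28 G1/S genes rose (camera adjusted p = 2.68e-35), with CDC6, which loads the replication helicase, at 2.08-fold. Of 34 p53 targets, 13 rose, or 14 when adjusted over the list alone, and 1 fell (camera adjusted p = 1.54e-05, but adjusted p = 0.0541 with an estimated correlation). Immediate-early genes rose in 17 of 23 members, and with adjustment over the list alone 19 rose and 1 fell (camera adjusted p = 2.80e-18, but adjusted p = 0.109 with an estimated correlation). T cell signalling genes fell in 11 of 17 members, or 14 when adjusted over the list alone (camera adjusted p = 6.68e-10, but adjusted p = 0.0541 with an estimated correlation), with the receptor chain genes CD247 at −0.42 ± 0.0598 and CD3D at −0.28 ± 0.0493. Summed T cell markers stood at 2219 ± 65.9 CPM after etoposide. Repair genes rose in 9 of 31 members and fell in 1, or 11 and 5 when adjusted over the list alone (camera adjusted p = 0.00157, but adjusted p = 0.228 with an estimated correlation), with BRCA2 at 1.55-fold. NF-κB targets were not called (camera adjusted p = 0.179), with 4 members up and 1 down, or 5 and 1 when adjusted over the list alone.

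Of 13914 genes tested in JURKAT, 1806 were called, 934 up and 872 down, and 99 of them changed at least 2-fold. Without JURKAT etoposide replicate 1 the count was 1095. Every etoposide library lay beyond every control for 30.2% of the tested genes, against 10% by chance.

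In the myeloid line THP1, JUN rose 13.5-fold, from 20.04 ± 1.92 to 271 ± 12.9 CPM (edgeR adjusted p = 1.50e-34). DUSP8, a kinase phosphatase gene, rose 12.3-fold, the neutrophil attractant gene IL8 7.44-fold and BTG2, a growth inhibitor gene, 4.98-fold. PIF1 fell from 23.5 ± 0.613 to 2.33 ± 0.172 CPM, a log2 change of −3.32 ± 0.128, and CCNB1 fell by 1.71 on the log2 scale. CDKN1A rose 1.40-fold and MDM2 fell by 0.28 on the log2 scale (SE 0.0482).

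All 31 G2/M genes fell in THP1 (camera adjusted p = 5.85e-48) and all 28 G1/S genes rose (camera adjusted p = 4.11e-29), with E2F2, a driver of S phase genes, at 2.01-fold. NF-κB targets rose in 21 of 25 members (camera adjusted p = 1.03e-21), with NFKBIA, the inhibitor of the pathway, at 3.63-fold, and 1 fell when adjusted over the list alone. Immediate-early genes rose in 18 of 25 members and fell in 2 (camera adjusted p = 3.83e-14). Of 40 p53 targets, 18 rose and 4 fell, or 18 and 5 when adjusted over the list alone (camera adjusted p = 0.000205, but adjusted p = 0.0701 with an estimated correlation). The topoisomerase and TDP list fell in 4 of 6 members (camera adjusted p = 0.00223, but adjusted p = 0.112 with an estimated correlation). Myeloid differentiation genes were not called (camera adjusted p = 0.201), with 1 member up, 5 down and 12 not past, the same when adjusted over the list alone. Summed myeloid markers stood at 4906 ± 164 CPM after etoposide.

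Of 13983 genes tested in THP1, 4333 were called, 1954 up and 2379 down, and 183 of them changed at least 2-fold. Every etoposide library lay beyond every control for 41.7% of the tested genes, against 10% by chance.

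U937, the other myeloid line, had IL8 as its largest riser among genes that met the naming rule. It rose 11.1-fold, from 32.6 ± 1.70 to 363 ± 22.4 CPM (edgeR adjusted p = 3.56e-27). JUN rose 9.49-fold, ATF3, a stress-induced repressor gene, 7.96-fold, and PTGS2, which makes prostaglandins, 5.88-fold. PIF1 fell by 2.79 and PLK1 by 2.18 on the log2 scale, and FNDC3B, an adipogenesis regulator gene, fell from 154 ± 3.59 to 32.1 ± 0.834 CPM. CDKN1A rose 2.71-fold, from 17.97 ± 1.58 to 48.5 ± 1.15 CPM, and MDM2 1.25-fold. MYC fell by 0.18 on the log2 scale (edgeR adjusted p = 0.00117), a call lost without U937 control replicate 1 (adjusted p = 0.0511).

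Of 31 G2/M genes, 30 fell in U937, or 31 when adjusted over the list alone (camera adjusted p = 1.00e-27, but adjusted p = 0.110 with an estimated correlation). G1/S genes rose in 25 of 28 members, the same when adjusted over the list alone (camera adjusted p = 2.09e-17), with CCNE2 at 2.85-fold. Immediate-early genes rose in 20 of 25 members and fell in 1, or 22 and 2 when adjusted over the list alone (camera adjusted p = 1.60e-14, but adjusted p = 0.110 with an estimated correlation). NF-κB targets rose in 18 of 23 members and fell in 2, or 19 and 3 when adjusted over the list alone (camera adjusted p = 3.94e-08, but adjusted p = 0.110 with an estimated correlation). Of 36 p53 targets, 20 rose and 5 fell, or 22 and 5 when adjusted over the list alone (camera adjusted p = 0.000191, but adjusted p = 0.110 with an estimated correlation), with PMAIP1, a death-promoting BCL2 family gene, at 3.09-fold. Repair genes rose in 15 of 31 members and fell in 3, the same when adjusted over the list alone (camera adjusted p = 0.00993, but adjusted p = 0.434 with an estimated correlation and 0.0716 with the replicate number as a block), with XRCC2 at 1.72-fold. Myeloid markers summed to 3825 ± 50.7 CPM after etoposide. Within the myeloid differentiation list, which was not called (camera adjusted p = 0.126), the granule protease genes ELANE and PRTN3 fell by 0.78 and 0.71 on the log2 scale.

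Of 13235 genes tested in U937, 5849 were called, 2930 up and 2919 down, and 383 of them changed at least 2-fold. Every etoposide library lay beyond both controls for 62.8% of the tested genes, against 20% by chance.

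**Figure D1:**
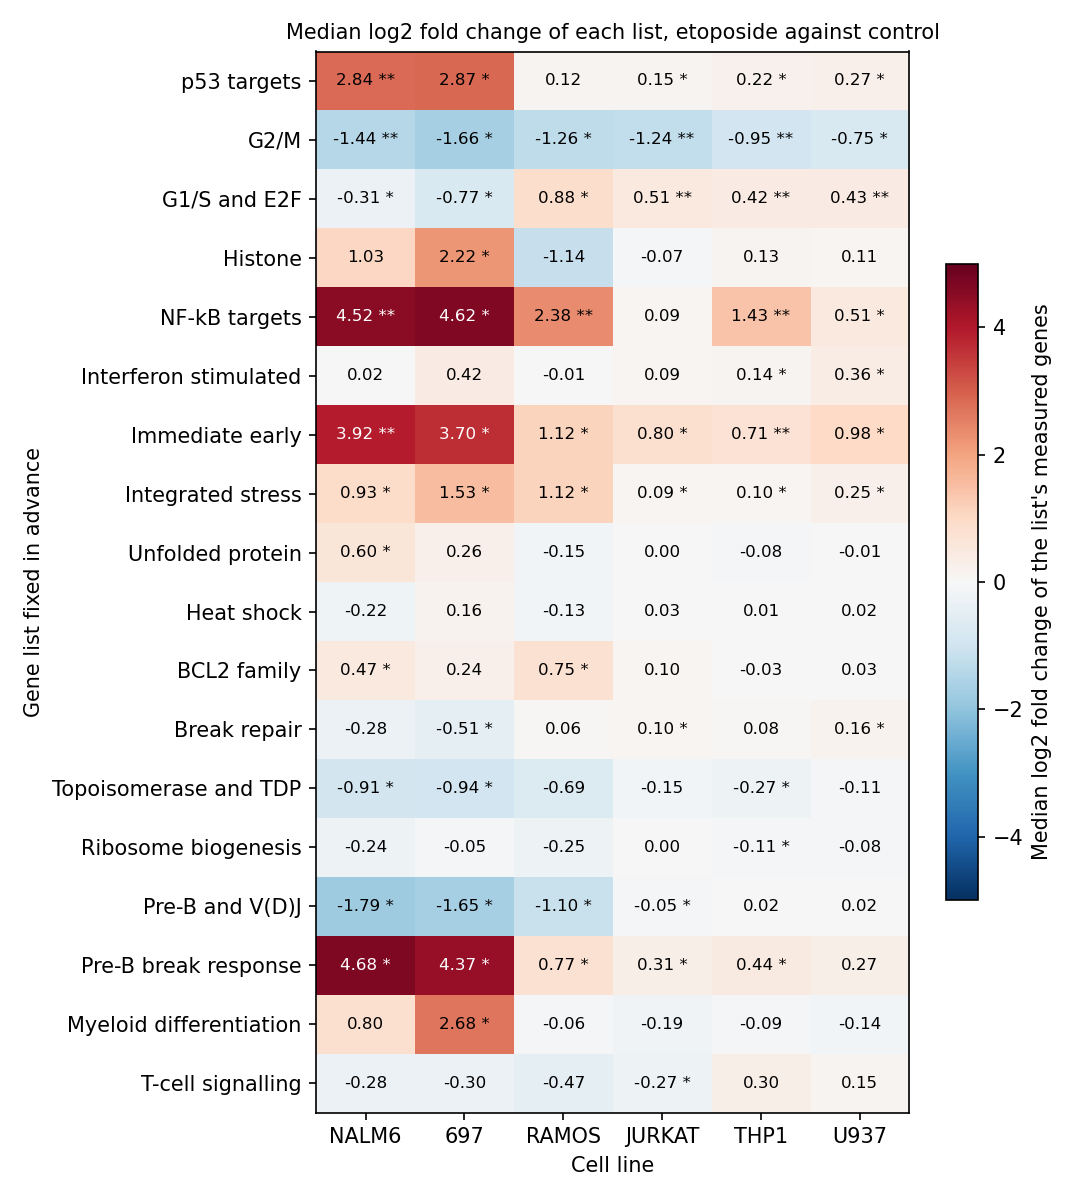
Median log2 fold change, etoposide minus control, of the measured members of 18 gene lists (vertical) in 6 cell lines (horizontal). Printed numbers are the medians, 1 star marks a camera adjusted p under 0.05 and a second star marks lists that kept it with an estimated correlation.

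A further question was which genes moved the same way in every line. Of 10265 genes tested in all 6 lines, 117 rose in each and 228 fell in each, against 1.40 and 1.96 expected of independent lists. Of the 30 G2/M genes tested in all lines, 28 were among the 228 that fell in each. PLK1 fell by between 1.90 in THP1 and 4.85 in RAMOS on the log2 scale, and CCNB1 by between 1.47 in U937 and 3.08 in NALM6. CDC20, which starts chromosome separation, fell by between 1.16 in THP1 and 3.68 in RAMOS. The shared rise held 8 of 17 immediate-early genes and 4 of 33 p53 targets. EGR1 rose by between 1.08 in RAMOS and 9.84 in NALM6 on the log2 scale, JUN by between 2.14 in JURKAT and 7.201 in NALM6, and CDKN1A by between 0.48 in THP1 and 5.33 in NALM6. NFKB2 was also called in every line, but its JURKAT rise of 0.37 (edgeR adjusted p = 0.0215) was lost without any 1 JURKAT library except control replicate 1, with adjusted p from 0.0546 without etoposide replicate 2 to 0.0917 without control replicate 2, and also with the replicate number as a block (adjusted p = 0.0608). Of the fixed genes, TOP2A, the topoisomerase II gene of dividing cells, fell in every line, from −1.89 ± 0.0552 in 697 to −0.51 ± 0.0444 in U937. TOP2B fell in 4 lines and did not pass in JURKAT (log2 change −0.11, adjusted p = 0.226) or U937 (−0.04, adjusted p = 0.577, and adjusted p = 0.00481 without U937 etoposide replicate 3 and 5.08e-05 with the replicate number as a block). MDM2 rose in NALM6, 697 and U937, by 2.69, 1.11 and 0.33 on the log2 scale, fell in RAMOS and THP1 and did not pass in JURKAT. MYC fell in every line except JURKAT, where it rose by 0.25 ± 0.0562. NALM6 and 697 shared 3745 rising genes, against 1863 expected of independent lists, and THP1 and U937 shared 1065, against 411. Pool and treatment coincided in NALM6 and 697, so their overlap holds any effect of the pool.

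**Figure D2:**
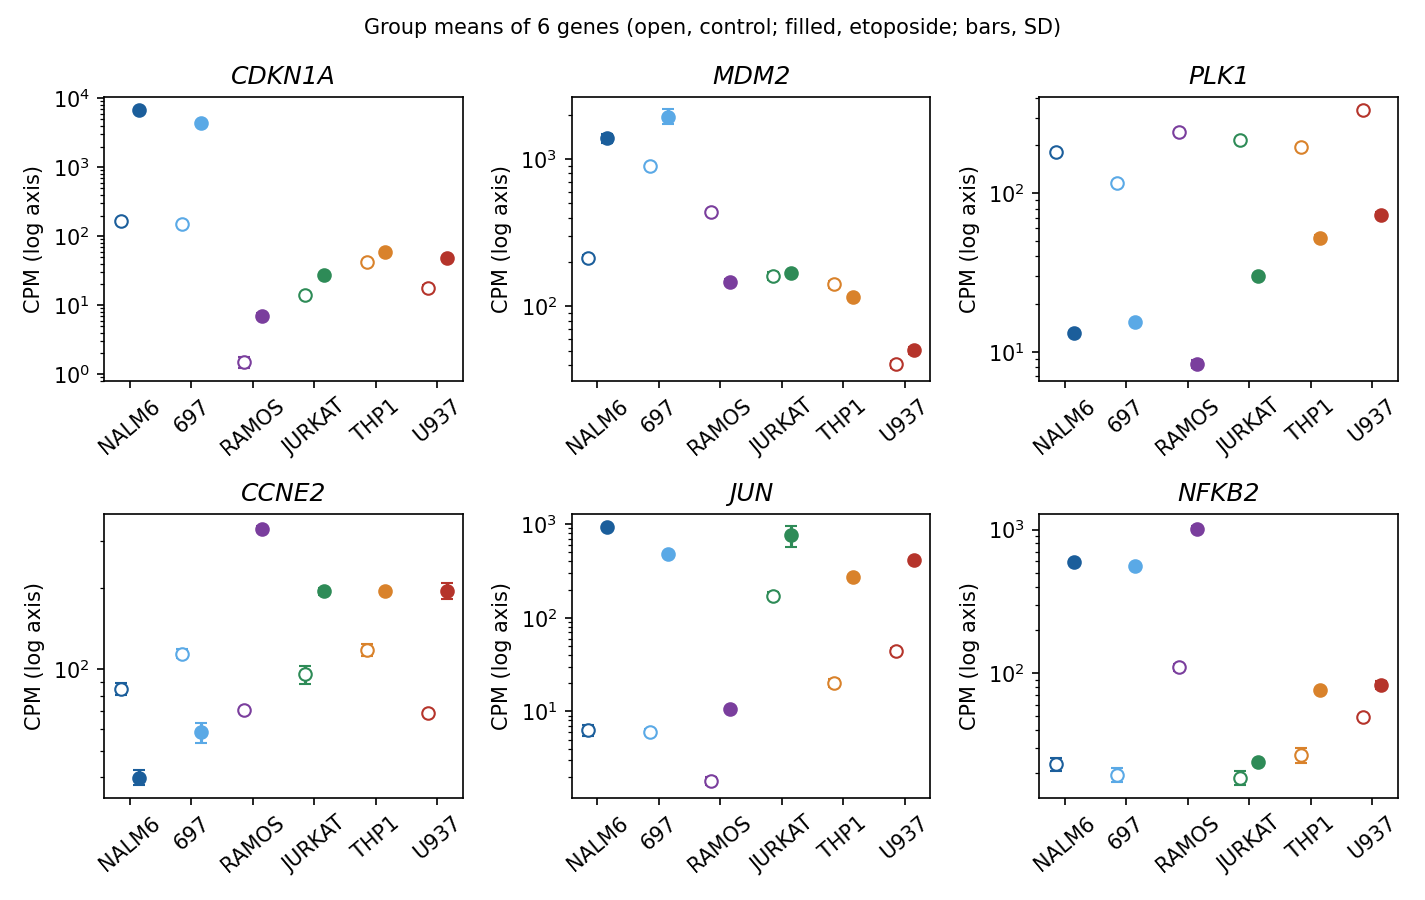
Mean CPM ± SD (vertical, log scale) of CDKN1A, MDM2, PLK1, CCNE2, JUN and NFKB2 in 6 cell lines (horizontal), with open points for control and filled points for etoposide groups. Each point is the mean of the 2 or 3 libraries of a group, and CDKN1A runs from 1.51 CPM in RAMOS controls to 6693 CPM in treated NALM6.

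The contrast of the pre-B lines with the 4 other lines asked whether the response itself differed. The rise of CDKN1A was larger in the pre-B lines by 3.81 ± 0.0858 on the log2 scale (edgeR adjusted p = 2.75e-47), and that of MDM2 by 2.24 ± 0.0510. MYC was lower by 2.11 ± 0.0548 and TOP2B by 1.78 ± 0.0490. RAG1 had the largest negative difference of the genes above the floor in all lines, at −3.98 ± 0.414, and FAM65B stood at −3.24 ± 0.365. PVRL4, an adhesion gene, had a difference of 8.45 ± 0.611, rising from 0.0885 to 21.4 CPM in NALM6 and from 0.0713 to 47.5 CPM in 697. Other genes with the largest differences had a line at or under the floor and are given by line. MMP2, a matrix protease gene, rose from no reads to 7.67 ± 0.988 CPM in NALM6, at least 143-fold, while JURKAT, THP1 and U937 did not pass. IL32, a cytokine gene, rose at least 88.9-fold in NALM6 and at least 54.2-fold in 697. Of the 26 genes that the rules picked for this contrast, 14 lost their call without some 1 library.

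Between the pre-B lines and the others, the p53 target list differed (camera adjusted p = 1.62e-24), with a larger change in 34 of 41 members and a median difference of 2.25 over the 33 members above the floor. G1/S genes differed the other way, with 27 of 28 members lower and 1 higher (camera adjusted p = 3.68e-21, median −1.19). NF-κB targets (18 of 26 higher, 1 lower, camera adjusted p = 1.41e-08) and immediate-early genes (21 of 25 higher, 2 lower, camera adjusted p = 1.96e-08) were raised more. Topoisomerase and TDP genes were all 6 lower (camera adjusted p = 0.000158). Adjustment over the list alone gave the same counts for these lists. G2/M genes were lower in 24 of 31 members and higher in 3 (camera adjusted p = 1.09e-05, but adjusted p = 0.0870 with an estimated correlation). Of 17008 genes tested, 9996 had a different effect, 5222 higher and 4774 lower in the pre-B lines, and 3823 differed at least 2-fold. The pre-B lines were the lines whose treatment coincided with library pool, so the contrast holds any effect of the pool.

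The contrast of the myeloid lines with RAMOS and JURKAT compared lines that each lay within 1 pool. Mitotic genes fell less in the myeloid lines, with TOP2A higher by 0.75 ± 0.0536 on the log2 scale (edgeR adjusted p = 9.22e-19) and 22 of 31 G2/M genes higher and 3 lower, or 24 and 3 when adjusted over the list alone (camera adjusted p = 4.44e-16). As a mean over the lines of each side, CDKN1A rose less, by 0.60 ± 0.0941, and MDM2 was higher by 0.78 ± 0.0611. In the joint fit CDKN1A rose by 2.19 in RAMOS, 0.94 in JURKAT, 0.49 in THP1 and 1.44 in U937. MDM2 changed by −1.575 in RAMOS, 0.08 in JURKAT, −0.28 in THP1 and 0.33 in U937. MYC changed by −1.47, 0.26, −0.65 and −0.18 in the same order, so RAMOS and JURKAT were not alike. MYC was higher by 0.19 ± 0.0592 (edgeR adjusted p = 0.0122), a call lost without JURKAT control replicate 3 (adjusted p = 0.0537) or U937 control replicate 2 (adjusted p = 0.0517). TOP2B was higher by 0.17 ± 0.0548 (edgeR adjusted p = 0.0202), a call lost without JURKAT control replicate 1 (adjusted p = 0.0543), JURKAT etoposide replicate 3 (0.0780), RAMOS etoposide replicate 2 (0.0605), U937 control replicate 1 (0.0558) or U937 etoposide replicate 3 (0.0688), and also with the replicate number as a block (adjusted p = 0.118). G1/S genes were lower in 19 of 28 members and higher in 2, or 21 and 2 when adjusted over the list alone (camera adjusted p = 1.63e-11). Integrated stress genes were lower in 10 of 20 members and higher in 2, or 13 and 2 when adjusted over the list alone (camera adjusted p = 3.56e-06), and BCL2 family genes in 8 of 15, with 2 higher, or 3 when adjusted over the list alone (camera adjusted p = 0.00214). BCL2A1 rose 40.5-fold in RAMOS and 1.16-fold in U937, and did not pass in THP1 (log2 change −0.35). Of 17008 genes tested, 3721 differed, 2111 higher and 1610 lower in the myeloid lines, and 465 differed at least 2-fold.

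NALM6 and 697 were compared to ask how alike the pre-B lines responded. MYC fell less in NALM6, by 2.00 ± 0.0909 on the log2 scale (edgeR adjusted p = 5.04e-28), and MDM2 rose more, by 1.58 ± 0.0831. VAV2, a signalling exchange factor gene, differed by 6.89 ± 0.294, rising from 0.0850 to 11.2 CPM in NALM6 and standing at 85.4 CPM in 697 controls. KIAA1462 differed by 6.62 ± 0.287 and SDK1, an adhesion gene, by 6.03 ± 0.398. RPS18 differed by −11.69 ± 3.49, but it has near-identical copies, its counts were erratic within groups, and the call was lost without 697 etoposide replicate 2 (adjusted p = 0.9999) and with the replicate number as a block (adjusted p = 0.0955). G1/S genes fell less in NALM6, with 23 of 28 members higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 1.41e-14). Heat shock genes were lower in NALM6 in 8 of 10 members, or 9 when adjusted over the list alone (camera adjusted p = 2.56e-07). Of 17008 genes tested, 5309 differed, 2568 higher and 2741 lower in NALM6, and 1365 differed at least 2-fold.

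THP1 and U937 were compared in the same way. CDKN1A rose less in THP1, by 0.96 ± 0.0873 on the log2 scale (edgeR adjusted p = 4.56e-13), and MYC fell more, by 0.48 ± 0.0862. AMH, a hormone gene, differed by 1.98 ± 0.250, as it rose in THP1 from 1.55 to 3.96 CPM and fell in U937 from 42.9 to 27.7 CPM. HCN2, an ion channel gene, differed by 2.14 ± 0.414 and TUBB2A, a tubulin gene, by 1.87 ± 0.447. NF-κB targets rose more in THP1, with 11 of 26 members higher and 2 lower, or 12 and 2 when adjusted over the list alone (camera adjusted p = 2.70e-06). G2/M genes were lower in THP1 in 10 of 31 members and higher in 1, or 15 and 1 when adjusted over the list alone (camera adjusted p = 0.000216, but adjusted p = 0.302 with an estimated correlation). Of 17008 genes tested, 2215 differed, 1014 higher and 1201 lower in THP1, and 222 differed at least 2-fold. The count was 1181 without U937 control replicate 1 and 1452 without U937 etoposide replicate 3, and it was 1037 with the replicate number as a block.

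The last comparison, chosen because trapped topoisomerase can block transcription along a gene, set genes spanning over 100 kb against genes spanning under 20 kb. Long genes were lower after etoposide by 0.31 on the log2 scale as a mean over the lines (permutation p = 1e-05, the smallest possible), and the difference lay below 0 in 6 of 6 lines. The difference was −0.41 in NALM6, −0.59 in 697, −0.43 in RAMOS and −0.28 in THP1, each with an exact p of 0.1, the smallest possible with these group sizes. It was −0.15 in U937 (exact p = 0.2) and −0.01 in JURKAT (exact p = 0.8), where it turned to 0.02 without JURKAT control replicate 1 and to 0.000159 without JURKAT etoposide replicate 2. With genes over 200 kb as the long genes it was −0.37 in U937 and −0.07 in JURKAT (exact p = 0.1 in each), and with a mean CPM of at least 5 it was −0.05 in JURKAT (exact p = 0.2). Over the 4 lines within 1 pool the mean was −0.22 (permutation p = 0.00025). Among called genes spanning over 200 kb, 88.9% were lower after etoposide in RAMOS, 96.9% in THP1, 89.7% in U937, 88.8% in JURKAT, 72.5% in 697 and 64.8% in NALM6. Among called genes spanning under 20 kb, the share was 37.8% in RAMOS, 26.1% in THP1, 49.0% in U937, 40% in JURKAT, 41.3% in 697 and 42.3% in NALM6.

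**Figure D3:**
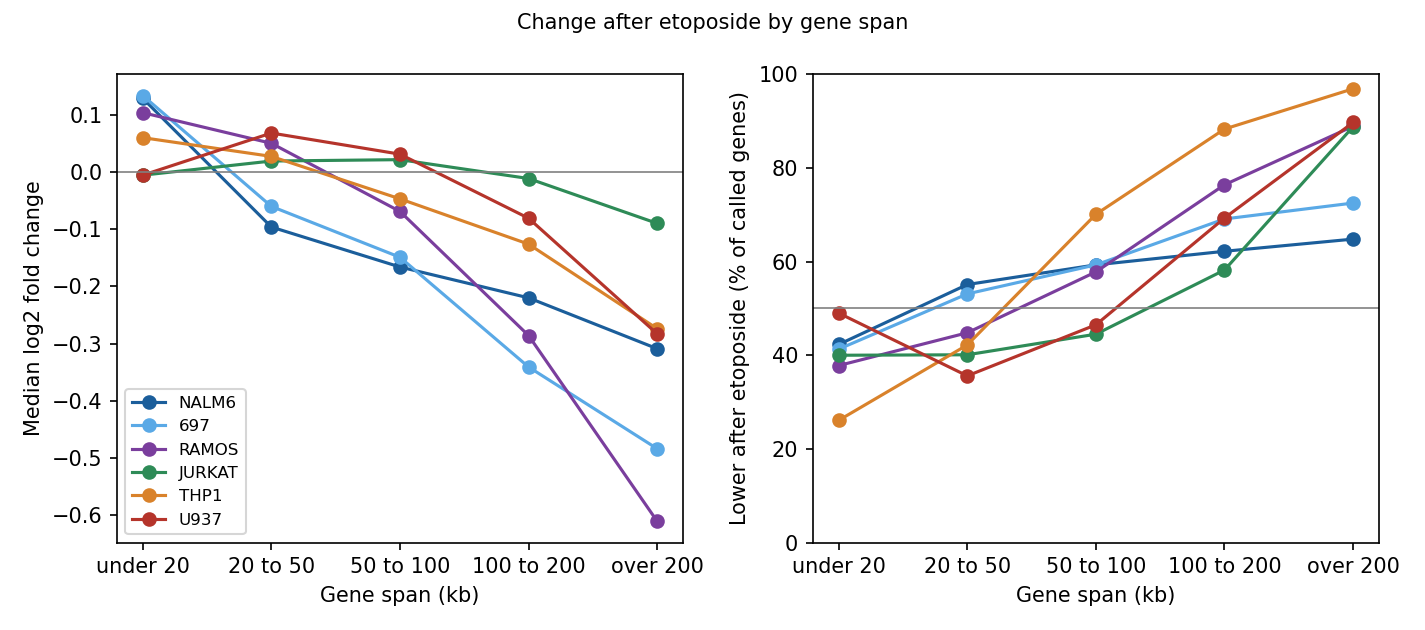
Median log2 fold change (left, vertical) and percent of called genes lower after etoposide (right, vertical) for genes grouped by gene span in kb (horizontal), 1 line per cell line. Each point is a span group, and the right panel reaches 96.9% in THP1 for spans over 200 kb.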

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

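The list medians, named genes and gene counts of the 4 contrasts in this part are given because the etoposide effect differed between cell lines by a test of the difference itself in the joint edgeR or camera model. Of the tests used here, those of JURKAT reads, library pool, scaling, and GC content or spliced length as the whole cause of the pre-B response were chosen after the result was seen, and the matching on expression level was planned but set as a test only then.

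The pre-B lines differed from the 4 other lines in 9996 genes. In 40 assignments of treatment within lines, the highest other count was 7561 and 1 assignment, the real one, reached 9996. Reassignment mixes treated and control libraries within a line, so it asks whether treatment had any effect. It cannot tell whether the effects differ between lines by chance, so nothing is concluded on chance for the gene count. For gene lists the real count of 12 was reached by 7 of the 40 assignments and the highest other was 13. A reassigned line holds unequal shares of treated libraries and so keeps part of the etoposide effect. The list counts therefore cannot decide on chance, which was not excluded. The other assignments with large gene counts kept a line at its real split, and the highest gene count among those with none was 3. List counts reached 12 among those with none, the real count. List medians that differed were p53 targets 2.25, NF-κB targets 2.23, immediate-early genes 2.49, the response to RAG breaks 2.38, histone genes 1.86, integrated stress genes 0.50 and unfolded protein genes 0.48. Lists lower in the pre-B lines were G2/M genes at −0.51, G1/S genes at −1.19, repair genes at −0.60, topoisomerase and TDP genes at −0.66 and pre-B and V(D)J genes at −0.99. With an estimated correlation the calls were lost for integrated stress (adjusted p = 0.114), unfolded protein (0.267), G2/M (0.0870), repair (0.114) and pre-B and V(D)J genes (0.114). Named genes that differed were PVRL4 8.45, CDKN1A 3.81, MDM2 2.24, RAG1 −3.98, FAM65B −3.24, MYC −2.11, TOP2B −1.78 and TOP2A −0.72.

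The size of the response in the pre-B lines was weighed first, and depth was argued against, since with every library thinned to 8.18 M counts the lower pre-B count of genes changed at least 2-fold was 2.08 times the highest count of the other lines. JURKAT reads in the shared pool accounted for 0% of the genes that rose at least 2-fold, and a trend on GC content and spliced length as the whole cause was argued against by a ratio of 1.96 after its removal. As a part of the cause it stayed open, because only 70.9% of the 2-fold genes in NALM6 kept that change. A lineage difference, or any other trait that set the pre-B lines apart, also stayed open. Neither was tested, and these lines cannot tell them apart. The library pool stayed open as a cause of the larger response. Genes changed at least 2-fold the same way in both pre-B lines were set against those called that way in RAMOS. Their overlap was 1.504 times that of independent lists for rises and 2.15 times for falls. A shared etoposide effect with a pool effect on top would give such an overlap too, so it cannot decide on the pool. Of those genes 1244 were shared against 726.5 expected, and 38.7% were not shared. Pool and treatment cannot be told apart for any of them, since no line had the same treatment in both pools. The 2-fold changes were 2583 up and 1243 down in NALM6, 3076 and 1409 in 697, and 834 and 1061 in RAMOS. They were 37 and 62 in JURKAT, 123 and 60 in THP1, and 250 and 133 in U937.

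The lower level of long genes was weighed second, and expression level was argued against by a difference of −0.31 with long and short genes matched on mean CPM. Spliced length and GC content as the whole cause were each argued against, as 18 of 18 differences within strata of each line lay below 0. A part that goes with GC content stayed open in the pre-B lines, where the differences within its strata ran from −0.28 to −0.17 in NALM6 and from −0.46 to −0.38 in 697. Library pool as the whole cause was argued against by a mean of −0.22 over the 4 lines within 1 pool. In NALM6 and 697 a part that goes with the pool cannot be told apart from treatment. A block to transcription along long genes, the reason for which the comparison was planned, stayed open and was not tested further.

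G1/S genes, higher in 4 lines and lower in the pre-B lines, were weighed last, though with an estimated correlation the calls were lost in NALM6 (adjusted p = 0.118), 697 (0.0565) and RAMOS (0.0652). Scaling of the libraries was argued against, because scaling moves all genes alike and the list median lay at least 0.32 from the median of all genes in each line. Library pool and treatment cannot be told apart for the pre-B lines, where the list median relative to all genes had a mean of −0.57. An arrest before S phase in the pre-B lines stayed open and was not tested.

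The myeloid lines differed from RAMOS and JURKAT in 3721 genes, where 1 of 40 assignments reached that count and the highest other was 336. As above, reassignment within lines cannot tell whether the effects differ between lines by chance. For gene lists 1 of 40 reached the real count of 9 and the highest other was 6, with the same limit. List medians that differed were G2/M genes 0.30, histone genes 0.73, topoisomerase and TDP genes 0.13, pre-B and V(D)J genes 0.41, G1/S genes −0.23, NF-κB targets −0.58, integrated stress genes −0.23, BCL2 family genes −0.29 and the response to RAG breaks −0.48. The NF-κB median over the members measured in each line was 2.38 in RAMOS, 0.09 in JURKAT, 1.43 in THP1 and 0.51 in U937. With an estimated correlation the calls were lost for topoisomerase and TDP genes (adjusted p = 0.183) and pre-B and V(D)J genes (0.416). Named genes were MDM2 0.78, TOP2A 0.75, MYC 0.19, TOP2B 0.17 and CDKN1A −0.60.

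NALM6 differed from 697 in 5309 genes. Chance was not excluded, and 4 of 40 assignments reached that count, with 9549 as the highest other. All 3 of those other assignments kept a line at its real split, which leaves that line's etoposide effect in the contrast. They therefore cannot decide the question, and the highest count with none was 42. For gene lists 27 of 40 assignments reached the real count of 7 and the highest other was 13. Reassigned lines keep part of the etoposide effect, so these counts cannot decide on chance either. List medians that differed were G1/S genes 0.50, immediate-early genes 0.43, unfolded protein genes 0.37, repair genes 0.23, pre-B and V(D)J genes 0.41, interferon genes −0.56 and heat shock genes −0.59. With an estimated correlation the calls were lost for immediate-early (adjusted p = 0.313), unfolded protein (0.0780), repair (0.313), pre-B and V(D)J (0.463) and interferon genes (0.0988). The pre-B and V(D)J call was lost without 697 etoposide replicate 1 (adjusted p = 0.0849), 697 etoposide replicate 2 (adjusted p = 0.0702) or NALM6 control replicate 1 (adjusted p = 0.0584). Named genes were VAV2 6.89, KIAA1462 6.62, SDK1 6.03, MYC 2.00, MDM2 1.58, TOP2B 0.67, CDKN1A 0.48, TOP2A 0.36 and RPS18 −11.69, the last with near-identical copies and uncertain.

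THP1 differed from U937 in 2215 genes, where 1 of 40 assignments reached that count and the highest other was 21. Here too, reassignment within lines cannot tell whether the effects differ between lines by chance. For gene lists 14 of 40 reached the real count of 4 and the highest other was 6. Since reassigned lines keep part of the etoposide effect, these counts cannot decide on chance. List medians that differed were NF-κB targets 0.27, G2/M genes −0.20, topoisomerase and TDP genes −0.27 and repair genes −0.06995, the last lost without U937 etoposide replicate 3 (adjusted p = 0.0548) and with the replicate number as a block (adjusted p = 0.0636). With an estimated correlation the calls were lost for G2/M (adjusted p = 0.302), topoisomerase and TDP (0.346) and repair genes (0.496). Named genes that kept their call without any 1 library were HCN2 2.14, AMH 1.98, TUBB2A 1.87, CDKN1A −0.96, MDM2 −0.61 and MYC −0.48, and FAM129C at 2.18 did so too. Calls lost without U937 control replicate 1 were NEURL 2.02 (adjusted p = 0.205), GRASP 1.94 (0.167), CGREF1 1.86 (0.336), TOP2A −0.28 (0.0768) and TOP2B −0.28 (0.0685). NEURL was also lost without U937 etoposide replicate 2 (adjusted p = 0.0595), and NEURL (0.0587), CGREF1 (0.116), TOP2A (0.0608) and TOP2B (0.0803) without U937 etoposide replicate 3. GRASP was also lost without THP1 control replicate 1 (adjusted p = 0.0558) or THP1 etoposide replicate 2 (adjusted p = 0.0535). DLL3 at 2.21 was lost without THP1 etoposide replicate 1 (adjusted p = 0.188) and CXCR5 at −2.60 without THP1 control replicate 3 (adjusted p = 0.0595). With the replicate number as a block the calls were lost for FAM129C (adjusted p = 0.0538), NEURL (0.105), GRASP (0.0765), CGREF1 (0.168), TOP2A (0.133) and TOP2B (0.153).

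Within single lines, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split called 10263 genes in NALM6, 8535 in RAMOS, 1806 in JURKAT and 4333 in THP1, and the highest other split called 0 in each by edgeR. For gene lists the real and highest other counts were 11 and 8 in NALM6, 8 and 7 in RAMOS, 9 and 9 in JURKAT, where 2 splits reached the real count, and 10 and 7 in THP1. In 697 and U937, with 5 libraries each, there were also 10 splits. The real and highest other counts there were 10257 and 1 genes and 12 and 10 lists in 697, and 5849 and 1 genes and 8 and 7 lists in U937. Of 100 assignments over all lines, 1, the real one, reached the 345 genes called the same way in every line, and the highest other was 0. These assignments ask only whether treatment had any effect, and no other assignment came near the real count. A line off its real split called at most 1 gene, so these assignments could not test how far lines share genes.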

How the results depend on the processing

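Every alternative in this part was chosen before the result was seen. No named gene called in both settings turned direction with RLE scaling, DESeq2, the replicate number as a block or 1 library left out. No list called in both settings did so with RLE scaling, no filter, the estimated correlation, the block or 1 library left out. Where a call was lost, the direction was not compared. The direction of the other genes was not compared between alternatives. The long-gene difference in JURKAT, −0.01 and not past its test, turned to 0.02 without JURKAT control replicate 1 and to 0.000159 without JURKAT etoposide replicate 2. With a 2-fold change also required, the counts were 3826 in NALM6, 4485 in 697, 1895 in RAMOS, 99 in JURKAT, 183 in THP1 and 383 in U937, and 3823, 465, 1365 and 222 in the contrasts of the pre-B, myeloid, NALM6 with 697 and THP1 with U937 lines, because that condition drops smaller changes. With the estimated correlation 29 of the 90 list calls remained past the threshold. The estimate lay below the preset 0.01 for some lists that lost their call. It was 0.0037 for NF-κB targets and −0.0156 for immediate-early genes in 697, where all 12 list calls were lost. Correlation between members alone thus does not account for every loss, and a lost call is not by itself a sign of correlated members. Within single lines, the block gained 3 list calls in U937, 1 in NALM6 and 1 in RAMOS, and lost 1 in U937. Without a filter 3 list calls were gained in NALM6, 2 in RAMOS and 2 in JURKAT, where 2 were lost. With RLE scaling, no filter or DESeq2 the gene counts stayed within 1.5 times of those reported. Leaving out 1 library at a time gave from 1095 genes (without JURKAT etoposide replicate 1) to 1582 in JURKAT, and from 1181 (without U937 control replicate 1) to 2533 in the contrast of THP1 with U937, with 1452 without U937 etoposide replicate 3; the cause was not tested. The other gene counts stayed within 1.5 times when any 1 library was left out. U937 without a control, or 697 without a treated library, left a group of 1, assumed to vary like the others. Replicate numbers showed no pairing, with correlations from −0.116 to 0.0585 between control and etoposide libraries of the same number. In JURKAT, libraries of different numbers reached 0.17 (control 2 with etoposide 3) and 0.109 (control 3 with etoposide 2). Pairing across numbers was not tested. The numbers of the treated 697 libraries differed between labels and file names, and the replicate block called 9655 genes with the former and 9951 with the latter. With the replicate number as a block the THP1 and U937 contrast had 1037 genes, and the other gene counts stayed within 1.5 times. Depth limited the counts of called genes, which with every library thinned to 8.18 M counts were 8993 in NALM6, 8379 in 697, 7137 in RAMOS, 1457 in JURKAT, 2399 in THP1 and 2978 in U937. Those changed at least 2-fold were then 3420, 3680, 1647, 88, 133 and 284 in the same order.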

Other observations

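All values here are of results seen before they were chosen for this part, and no tests were added for them.

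The stress lists gave the following values in single lines. Integrated stress genes rose in 15 of 19 members in NALM6 and fell in 4 (camera adjusted p = 7.81e-05, but adjusted p = 0.0558 with an estimated correlation), with DDIT3, a stress transcription factor gene, at 3.84 on the log2 scale. They rose in 15 of 20 members in 697 and fell in 2 (camera adjusted p = 0.000204, but adjusted p = 0.0606 with an estimated correlation). In JURKAT 7 of 19 rose, with 1 down when adjusted over the list alone (camera adjusted p = 3.18e-05, but adjusted p = 0.0524 with an estimated correlation). In THP1 7 of 20 rose and 3 fell, or 10 and 3 over the list alone (camera adjusted p = 0.00223, but adjusted p = 0.0701 with an estimated correlation). In U937 9 of 19 rose and 2 fell (camera adjusted p = 0.00325, but adjusted p = 0.114 with an estimated correlation). Unfolded protein genes rose in 9 of 14 members in NALM6 and fell in 2 (camera adjusted p = 0.00315, but adjusted p = 0.138 with an estimated correlation), with the chaperone gene HSPA5 at 1.19 ± 0.0391. They were not called in 697 (camera adjusted p = 0.283), RAMOS (0.629), JURKAT (0.902), THP1 (0.223) or U937 (0.643, with a median of −0.01 and a mean of 0.07). Heat shock genes were not called in NALM6 (0.178), 697 (0.283), RAMOS (0.573), JURKAT (0.902, median 0.03 and mean −0.01), THP1 (0.495) or U937 (0.443), yet HSPD1, a mitochondrial chaperone gene, fell by 1.23 in NALM6.

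Interferon genes rose in 12 of 28 members in U937 and fell in 2, or 13 and 2 over the list alone (camera adjusted p = 0.00719, but adjusted p = 0.397 with an estimated correlation). In THP1 7 of 29 rose (camera adjusted p = 0.0327, but adjusted p = 0.112 with an estimated correlation), a call lost without THP1 control replicate 1 (adjusted p = 0.0597), THP1 control replicate 2 (adjusted p = 0.0622) or THP1 etoposide replicate 1 (adjusted p = 0.0534). The list was not called in NALM6 (0.346), 697 (0.0625), RAMOS (0.718, median −0.01 and mean 0.02) or JURKAT (0.425), though IRF7, an interferon regulator gene, rose by 3.05 ± 0.0870 in 697. BCL2 family genes rose in 8 of 14 members in NALM6 and fell in 3 (camera adjusted p = 0.0316, but adjusted p = 0.135 with an estimated correlation), and rose in 8 of 14 in RAMOS and fell in 4 (camera adjusted p = 0.0181, but adjusted p = 0.273 with an estimated correlation). They were not called in 697 (0.198), JURKAT (0.0688, but 0.0497 without JURKAT control replicate 1 and 0.0414 without JURKAT etoposide replicate 3), THP1 (0.495, median −0.03 and mean 0.06) or U937 (0.558). BCL2, the survival gene, fell by 1.30 in NALM6 and by 2.28 in 697. Ribosome biogenesis genes fell in 11 of 22 members in THP1 and rose in 1, or 11 and 2 over the list alone (camera adjusted p = 0.0266, but adjusted p = 0.193 with an estimated correlation), a call lost without THP1 control replicate 1 (adjusted p = 0.0609). They were not called in NALM6 (0.198), 697 (0.283), RAMOS (0.147), JURKAT (0.437) or U937 (0.198).

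Of the remaining lists, topoisomerase and TDP genes fell in 5 of 6 members in NALM6 and rose in 1 (camera adjusted p = 0.00552, but adjusted p = 0.215 with an estimated correlation). They were not called in RAMOS (0.0513), where the list passed without any 1 RAMOS library except control replicate 1 (adjusted p from 0.0347 to 0.0470). In JURKAT (0.0667) it passed without JURKAT control replicate 3 (adjusted p = 0.0350) or JURKAT etoposide replicate 1 (adjusted p = 0.0399), and it was not called in U937 (0.443). The response to RAG breaks rose in 2 of 6 members in JURKAT, or 3 over the list alone, and fell in 1 (camera adjusted p = 0.0427, but adjusted p = 0.1999 with an estimated correlation), a call lost without JURKAT control replicate 2 (adjusted p = 0.0785), JURKAT control replicate 3 (adjusted p = 0.0529) or JURKAT etoposide replicate 1 (adjusted p = 0.0544), or with no filter on low counts (adjusted p = 0.0695). It rose in 3 of 5 in THP1 and fell in 1 (camera adjusted p = 0.00712, but adjusted p = 0.102 with an estimated correlation), and in U937 it was not called (0.0753), where it passed without U937 control replicate 1 (adjusted p = 0.0416). Pre-B and V(D)J genes fell in 5 of 19 members in JURKAT, or 6 over the list alone, and rose in 1 (camera adjusted p = 0.0158, but adjusted p = 0.228 with an estimated correlation and 0.0646 with no filter on low counts), and were not called in THP1 (0.273) or U937 (0.180). Repair genes were not called in NALM6 (0.221), RAMOS (0.393) or THP1 (0.389). Histone genes, whose copies make their reads uncertain, were not called in NALM6 (0.223), RAMOS (0.324), JURKAT (0.247), THP1 (0.434) or U937 (0.748). Myeloid differentiation genes were not called in NALM6 (0.178), RAMOS (0.720) or JURKAT (0.902), and T cell signalling genes were not called in NALM6 (0.652), 697 (0.373), RAMOS (0.892), THP1 (0.223) or U937 (0.643).

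In the authors' deposited table of NALM6, 9474 genes had an adjusted p under 0.05, and the deposited fold change had the sign of the counts in 92.6% of the genes called here. Of the genes called here and listed in the authors' deposited table of NALM6, 7461 were called in both and 2786 only here. The authors' deposited table gave a log2 change of 1.77 for MDM2 in NALM6, against 2.69 from the counts. The authors' deposited table of each other line had the sign of the counts in 100% of the genes called here. In the authors' deposited table of NALM6, JURKAT, THP1 and U937 the Wald statistic had the sign opposite to the fold change in every gene listed.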
